A study of Mus musculus with 10 samples.

How the data were processed

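RNA was sequenced from primary mouse peritoneal macrophages in 10 libraries of 3 groups. Per the labels, 4 libraries came from young wild-type mice (replicates A, B, C and E), 3 from aged wild-type mice (replicates 3, 4 and 6) and 3 from aged Trem1-/- mice (replicates 1, 2 and 3). The labels name no young Trem1-/- group, no age in months, no sex, no batch and no isolation or sorting step, and they do not say that the libraries came from separate mice. The p-values therefore measure the spread between these samples, which may be technical.

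The labels describe RNA extraction with a Qiagen column kit, full-length cDNA from a stranded Takara kit and libraries from a NEBNext Ultra kit. The submitters' processing notes list the genome build GRCm38, fastp, STAR, featureCounts 1.5.0-p3 and DESeq2 1.20.0; their order, parameters and annotation release are not given in the sources used here. Strand-aware counting is likewise not given there, so values of genes whose exons overlap another gene are uncertain.

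The deposited table held 54532 genes. The authors gave 1 column of normalized counts per library and their mean, both in units of signal. In each library column every value was a whole multiple of 1 number within a tolerance of 1e-06 (100% of values), so whole reads were recovered by dividing by it. The authors' DESeq2 comparison of aged with young wild type was deposited as a log2 fold change, its standard error, a score (the Wald statistic), a p-value and an adjusted p-value, which 17359 genes carried. Its log2 fold change differed from the log2 ratio of the group means by a median of 0.00651 for genes with a mean of at least 10. No deposited comparison involving the Trem1-/- libraries was used here. Reads were recovered for 2663744 to 5603498 reads per library. A floor of 3 reads corresponds to 1.85 to 3.84 normalized counts; floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The table gave gene symbols, of which 53825 (98.7%) matched GENCODE M21 on GRCm38, used for identifiers, coordinates and exon overlaps. The other 707 symbols, of which 27 look like dates, have no coordinates here, and 17593 genes held no read.

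Since the table holds normalized values, the test was limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), the choice fixed for that case. All 10 libraries entered 1 model with 3 groups and a shared estimate of the spread. Genes with a mean of at least 10 normalized counts over the 10 libraries were tested (11506 genes), with Benjamini-Hochberg adjustment at 0.05 within each comparison. Log2 fold changes on this scale understate changes of genes with few counts. The 3 comparisons were aged against young wild type, aged Trem1-/- against aged wild type, and aged Trem1-/- against young wild type. Trem1 was compared by exact two-sided permutation tests of its normalized counts. The relation of the first to the second comparison across genes was set beside 100 simulations of unchanged groups.

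Tested on simulated data with the means, spread and depths of the 10 libraries, limma recovered 10.4% of 1.5-fold, 55.2% of 2-fold and 84.8% of 4-fold changes with the sample numbers of the first comparison, and 5.97%, 47.8% and 84.8% with those of the second. In both tests 0 of 30 unchanged gene lists were called. Genes were drawn independently of each other there, so lists whose members vary together were not tested. Beside a shifted list, 67, 67 and 66 genes were changed 1.5-, 2- and 4-fold, of 11368 and 11356 tested. That is a smaller share than limma called in these comparisons. The adjusted threshold depends on that share, so recovery in the data may differ.

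Gene lists were fixed before the data were examined, as were samples, main tests, most alternatives and the rule for named genes. The 34 lists were TREM1 receptor signalling, Trem1 chromosomal neighbours, glycolysis, the pentose phosphate pathway, purine synthesis, the TCA cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, inflammatory mediators, interferon-stimulated genes, MHC class II presentation, large and small peritoneal macrophage genes, and markers of B cells, T and NK cells, mast cells, neutrophils, eosinophils, dendritic cells, mesothelial cells and fibroblasts, and erythroid cells. The others were cholesterol synthesis, cholesterol efflux and lipid storage, phagocytic receptors and complement, lysosome, cell cycle, senescence, immediate-early and heat-shock genes, NRF2 antioxidant genes, the integrated stress response, the NAD and kynurenine pathway, arginase and alternative activation, the circadian clock, and Y-linked genes with Xist. Lists with at least 3 measured members (32 lists) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison; camera with an estimated correlation and fry stand beside it. None of the lists called with the preset correlation was called with the estimated one, in any of the 3 comparisons.

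Named genes were chosen by rule. They are Trem1; the 10 largest rises and 10 largest falls (5 and 5 for aged Trem1-/- against young wild type) among genes with an adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between the libraries of the 2 groups, leaving out Gm and Rik symbols, identifiers, pseudogenes and immunoglobulin or T cell receptor variable segments; and up to 4 members of each list with the smallest p (2 where none passed). Some genes that met this rule are not reported here. Named genes (222) were checked for stretches of 31 bases shared with other genes' transcripts, and 25 shared at least 20% of theirs.

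Alternatives covered edgeR 4.0.16 quasi-likelihood tests on the recovered reads with TMM and with median-of-ratios factors, DESeq2 1.42.0, limma-voom with sample weights, limma-trend after TMM rescaling, a pseudocount of 0.1, no filter, a mean CPM filter of 1, an added fold threshold, fits of only the 2 groups compared, and leaving out each library in turn. Of these, edgeR with TMM and limma-trend after TMM rescaling were chosen after seeing the data, as was the correction for GC content and length. With all reads recovered as whole numbers, edgeR with TMM called 1879 genes higher and 1993 lower in aged against young wild type, 1158 and 945 in aged Trem1-/- against aged wild type, and 60 and 33 in aged Trem1-/- against young wild type. A correction for GC content and transcript length used loess with a span of 0.5 over the 99.3% of tested genes with both values. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for tables, exact tests and plots.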

Results

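Gene expression was measured by RNA sequencing in peritoneal macrophages, the phagocytes of the abdominal cavity, from young wild-type (n = 4 libraries), aged wild-type (n = 3 libraries) and aged Trem1-/- mice (n = 3 libraries). Values below are normalized read counts, given as mean ± SD over these libraries, and log2 fold changes with their standard error (SE). Recovered reads per library were 4045492, 5603498, 2939414 and 3130260 in young wild-type replicates A, B, C and E. They were 2663744, 3172204 and 3614156 in aged wild-type replicates 3, 4 and 6, and 3471464, 4628187 and 3138568 in libraries 1, 2 and 3 labelled Trem1-/-. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 4.49 to 21.1), so none was counted as a second run of the same library; separate preparations from 1 mouse would also exceed that noise.

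Trem1, which encodes an activating receptor that amplifies inflammatory signals in myeloid cells, was read in all 10 libraries, those labelled Trem1-/- included. The gene (ENSMUSG00000042265.13, GRCm38 chromosome 17, 48232768 to 48246924, plus strand) shares exonic bases with 0 other annotated genes. It had 14.8 ± 6.98 normalized counts in young wild type (n = 4), 35.4 ± 25.4 in aged wild type (n = 3) and 47.7 ± 50.5 in the libraries labelled Trem1-/- (n = 3). The last group held 23.5, 106 and 13.8 normalized counts in replicates 1, 2 and 3, from 23, 132 and 12 reads. Its mean was 1.35 times that of aged wild type, with an exact two-sided permutation p of 0.9; the smallest p this design allows is 0.1. Without replicate 2 of that group the ratio was 0.526, so its direction rested on that library. Aged and young wild type differed with an exact p of 0.114 (smallest possible 0.0571). Counts per gene cannot check a deletion that leaves part of the transcript, so the genotype is used as labelled.

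**Figure D1:**
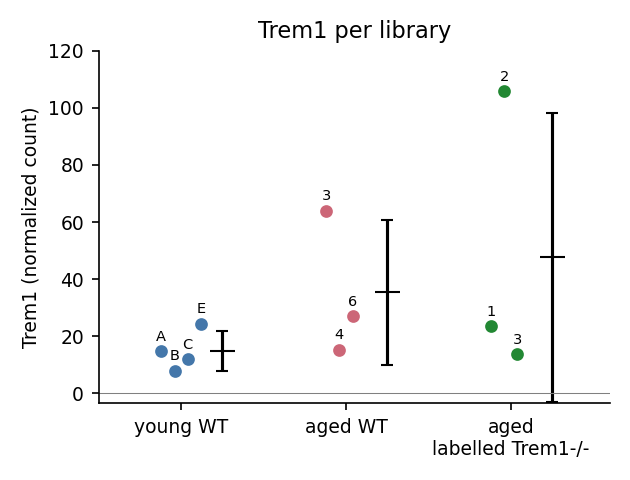
Normalized counts of Trem1 in each library (points) with group means and SD, for young wild type (n = 4), aged wild type (n = 3) and aged libraries labelled Trem1-/- (n = 3). Replicate 2 of the last group is the highest of the 10 libraries at 106.

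Principal components of all tested genes separated the aged wild-type libraries from the other groups. The first component held 48.2% of the variance, with young wild type from -53.4 to -28.4, aged wild type from 36.2 to 71.1 and the libraries labelled Trem1-/- in between, from -10.6 to 0.17. The second component held 10.99%. Aged wild-type libraries also stood apart in composition. The noncoding RNA gene Gm26917 took 8.38% to 12.9% of their reads against 4.999% to 5.70% elsewhere, and mitochondrial transcripts took 3.17% to 5.26% against 1.19% to 2.39%. Immunoglobulin transcripts took 0.347% to 0.595% in aged wild type, 0.0621% to 0.14% in young wild type and 0.181% to 0.381% in the libraries labelled Trem1-/-.

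**Figure D2:**
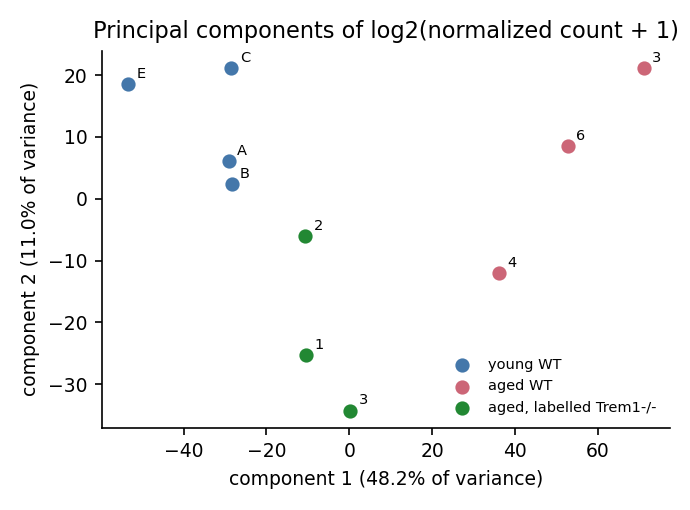
First and second principal components of log2(normalized count + 1) for the 10 libraries, colored by group. Aged wild-type libraries lie at 36.2 to 71.1 on component 1 and the other 7 libraries at or below 0.17.

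The comparison of aged with young wild type asks how peritoneal macrophage preparations change with age. Genes of resident macrophage identity, phagocytosis, lysosomes and cell division fell in aged wild type, while markers of lymphocytes and mitochondrially encoded transcripts rose. Adgre1, the gene of the macrophage surface marker F4/80, fell from 4707 ± 468 to 2115 ± 371 normalized counts (log2 fold change -1.16 ± 0.13 SE, limma adjusted p = 0.000214). Top2a, the topoisomerase of dividing cells, fell from 509 ± 210 to 102 ± 47.3 (-2.32 ± 0.33). Ighd, the heavy chain of IgD on mature B cells, rose from 89.4 ± 36.8 to 532 ± 150 (2.63 ± 0.29). With limma 1647 genes were higher and 2190 lower in aged wild type, together 33.3% of the 11506 tested, and 880 and 834 of them changed more than 2-fold. The authors' deposited table called 1847 genes higher and 1950 lower.

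The largest rises included Aldh1l2, a mitochondrial folate enzyme (ENSMUSG00000020256.14, chromosome 10, 83487450 to 83534140), which went from 2.23 ± 1.22 to 160 ± 60.0 normalized counts (log2 fold change 5.64 ± 0.45, limma adjusted p = 9.96e-05). Its exons overlap D10Wsu102e. Krt18, an epithelial keratin (chromosome 15, 102028180 to 102032027), rose from 5.24 ± 6.13 to 228 ± 158 (5.196 ± 0.78). Others were Hbb-bs, AF067061, Cyp11a1, Eppk1, F11r, Gnb3 and Robo1, with log2 fold changes of 4.28 to 4.88. Hbb-bs, a beta-globin gene, lost its call without young replicate E or aged wild-type replicate 4 (adjusted p up to 0.0753). AF067061 shares 22.0% of its sequence with Gm21761. The largest falls were led by Shank3, a scaffold protein of synapses (ENSMUSG00000022623.16, chromosome 15, 89499623 to 89560261), from 358 ± 139 to 22.2 ± 11 (-3.96 ± 0.40, limma adjusted p = 0.000126). Lyve1, the hyaluronan receptor of lymphatic vessels and of some resident macrophages, fell from 293 ± 116 to 34.1 ± 20.5 (-3.12 ± 0.65). E2f8, a transcription factor of the cell cycle, fell by 2.85 ± 0.27 on the log2 scale. The others, from -3.45 to -2.64, were Myh7, Hspa1a, Anln, Prr11, Hspa1b, Stab1 and Vcan. Myh7 shares 31.7% of its sequence with Myh6, Hspa1a and Hspa1b share 63.8% and 67.6% of theirs, and Stab1 overlaps Nt5dc2.

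Markers of lymphocytes were higher in each aged wild-type library, and those of some other cell types followed single libraries. B cell markers rose, with 18 of 19 measured members higher (19 adjusted over the list alone; camera adjusted p = 3.61e-12, and adjusted p = 0.499 with an estimated correlation). Blnk, an adaptor of B cell receptor signalling, rose by 1.54 ± 0.16 and Blk, a B cell kinase, by 2.29 ± 0.27 on the log2 scale. T and NK cell markers rose in 12 of 13 members (13 adjusted over the list alone; camera adjusted p = 1.36e-07, and adjusted p = 0.499 with an estimated correlation). Lck, the T cell receptor kinase, rose from 12.7 ± 1.72 to 82.5 ± 38.4 and Cd8a, the coreceptor of cytotoxic T cells, from 3.87 ± 2.19 to 35.6 ± 5.99. Mesothelial and fibroblast markers had a median of 2.54 with 2 of 9 members higher (2 adjusted over the list alone; camera adjusted p = 0.0204, and adjusted p = 0.578 with an estimated correlation), a call lost without young replicate B or aged wild-type replicate 6 (adjusted p up to 0.0509). Erythroid markers had a median of 4.10 with 5 of 6 members higher (6 adjusted over the list alone; camera adjusted p = 0.0132, and adjusted p = 0.578 with an estimated correlation). Without aged wild-type replicate 4, where alpha- and beta-globin transcripts took 0.618% of reads against 0.0143% and 0.0133% in replicates 3 and 6, their median was 2.28 and the list had an adjusted p of 0.123. Mast cell markers had a median of 1.98 but did not pass (camera adjusted p = 0.0817). Mesothelial and fibroblast scores were 3.37, 1.36 and 3.55 in aged wild-type replicates 3, 4 and 6, and within that range in young replicate C (3.01) and Trem1-/- replicate 2 (3.21). Mast cell scores were 1.57, 1.19 and 2.58 in the former and 1.88 and 2.196 in the other two.

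Genes of macrophage identity and clearance functions fell together. Of 23 genes of large resident peritoneal macrophages, 19 fell and 1 rose (19 and 1 adjusted over the list alone; camera adjusted p = 7.5e-09, and adjusted p = 0.499 with an estimated correlation). F5, coagulation factor V, fell from 9866 ± 739 to 3361 ± 1102, and Laptm5, a lysosomal membrane protein, fell by 1.24 ± 0.15 on the log2 scale. Phagocytic receptors and complement fell in 16 of 25 members and rose in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 1.45e-05, and adjusted p = 0.499 with an estimated correlation). Itgb2, a subunit of complement receptor 3, fell by 1.25 ± 0.14 and C1qc, a chain of complement C1q, by 1.33 ± 0.16 on the log2 scale. Lysosomal genes fell in 22 of 28 members (22 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.71e-08, and adjusted p = 0.499 with an estimated correlation). Gusb, beta-glucuronidase, fell by 1.60 ± 0.16 and Grn, progranulin, by 1.25 ± 0.14. Cholesterol efflux and lipid storage genes fell in 10 of 17 members and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00778, and adjusted p = 0.499 with an estimated correlation). Lpl, lipoprotein lipase, fell from 2176 ± 377 to 371 ± 90.8 and Fabp4, a fatty acid carrier, from 848 ± 161 to 209 ± 54.2. Mylip, which marks the LDL receptor for degradation, rose by 0.94 ± 0.15.

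Cell cycle genes were mostly lower, while metabolic lists moved both ways. Cell cycle genes fell in 24 of 26 members (25 adjusted over the list alone; camera adjusted p = 1.34e-10, and adjusted p = 0.499 with an estimated correlation), with a median of -1.89. Stmn1 and Bub1b, a microtubule regulator and a spindle checkpoint kinase, fell by 2.18 ± 0.31 and 2.10 ± 0.33 on the log2 scale. Nuclear-encoded oxidative phosphorylation genes fell in 21 of 48 members (22 adjusted over the list alone; camera adjusted p = 1.52e-05, and adjusted p = 0.578 with an estimated correlation), Ndufb8 of complex I by 0.66 ± 0.12. Transcripts encoded in the mitochondrial genome rose in 11 of 13 members (12 adjusted over the list alone; camera adjusted p = 0.000166, and adjusted p = 0.578 with an estimated correlation). The cytochrome oxidase subunit mt-Co1 rose by 1.002 ± 0.28, while the list score was 2.14 in aged wild-type replicate 4 and 0.46 and 0.57 in the other two. Glycolysis genes fell in 10 of 21 members and rose in 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0359, and adjusted p = 0.578 with an estimated correlation), a call lost without young replicate E or aged wild-type replicate 6 (adjusted p up to 0.0551). Hk3, a hexokinase, fell by 1.25 ± 0.19. Genes of the NAD and kynurenine pathway rose in 6 of 15 members and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.499 with an estimated correlation). Kynu and Kmo, enzymes that break down kynurenine, rose by 1.87 ± 0.34 and 0.99 ± 0.20, and Nadk, NAD kinase, fell by 0.59 ± 0.09.

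MHC class II presentation genes rose in 10 of 15 members and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00252, and adjusted p = 0.499 with an estimated correlation). H2-Ob and H2-DMb2, peptide-loading regulators prominent in B cells, rose by 2.03 ± 0.29 and 1.89 ± 0.22, beside the rise of B cell markers, while Ctss, the cathepsin that trims the invariant chain, fell by 0.71 ± 0.10. Senescence-associated genes fell in 6 of 14 members (8 adjusted over the list alone; camera adjusted p = 0.0132, and adjusted p = 0.499 with an estimated correlation). The members named were Cdkn2c, a cell cycle inhibitor induced in dividing cells (-2.34 ± 0.30), Glb1, lysosomal beta-galactosidase (-1.31 ± 0.18), Igfbp4 and Plaur. Igfbp4 lost its call without aged wild-type replicate 3 or 6 (adjusted p up to 0.0667). Glb1 is also in the lysosome list, so the falls of these lists are not independent. NRF2 antioxidant genes fell in 8 of 19 members and rose in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0218, and adjusted p = 0.578 with an estimated correlation), a call lost without aged wild-type replicate 3 or 6 (adjusted p up to 0.118). Hmox1, haem oxygenase 1, fell by 1.19 ± 0.25 and Gclc, for glutathione synthesis, rose by 0.92 ± 0.16.

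The other 16 lists tested did not pass with camera, from the TCA cycle (adjusted p = 0.0565) to the integrated stress response (adjusted p = 0.833). Of these, the TCA cycle, mast cell markers and immediate-early and heat-shock genes passed after TMM rescaling or with some library left out, and the TCA cycle and small peritoneal macrophage markers passed with fry (lower, adjusted p = 0.0353). TREM1 receptor signalling had 6 members higher and 3 lower of 19 (6 and 4 adjusted over the list alone; camera adjusted p = 0.728); its median of -0.07 and its test differed in sign. In it Tyrobp, the adaptor DAP12, fell by 1.24 ± 0.15 and Syk, a kinase downstream of it, rose by 1.001 ± 0.14. Syk rose beside the B cell markers, and which cells carried its reads was not tested. Of 14 small peritoneal macrophage markers 7 fell and 2 rose (8 and 3 adjusted over the list alone), with a median of -0.96. Among them Ccr2, a chemokine receptor of monocytes, fell by 1.19 ± 0.14 and Plac8 rose by 1.95 ± 0.31. Camera adjusted p was 0.11 for this list. It was 0.118 for purine synthesis, 0.195 for Trem1 chromosomal neighbours, 0.245 for immediate-early and heat-shock genes, 0.301 for cholesterol synthesis, 0.312 for the circadian clock, 0.587 for the pentose phosphate pathway and 0.67 for dendritic cell markers and for arginase and alternative activation. It was 0.728 for interferon-stimulated genes, inflammatory mediators and Y-linked genes with Xist. Dendritic cell markers had a median of -0.11 and a mean of 0.12. Neutrophil and eosinophil markers had 2 measured members each and were not tested. Csf3r, a neutrophil growth factor receptor, fell by 1.21 ± 0.23, and Il5ra, the interleukin 5 receptor of eosinophils and some B cells, rose by 2.69 ± 0.38.

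The p-values of aged against young wild type rest on 3 and 4 libraries. Sequence shared with other genes also covers at least 20% of mt-Co1, Stmn1, H2-DMb2, Csf3r and Mcm7 and of the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, and exons of Hk3 and Glb1 overlap Unc5a and Tmppe. Of the 20 genes with the largest changes, 19 kept their call when any 1 library was left out.

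**Figure D3:**
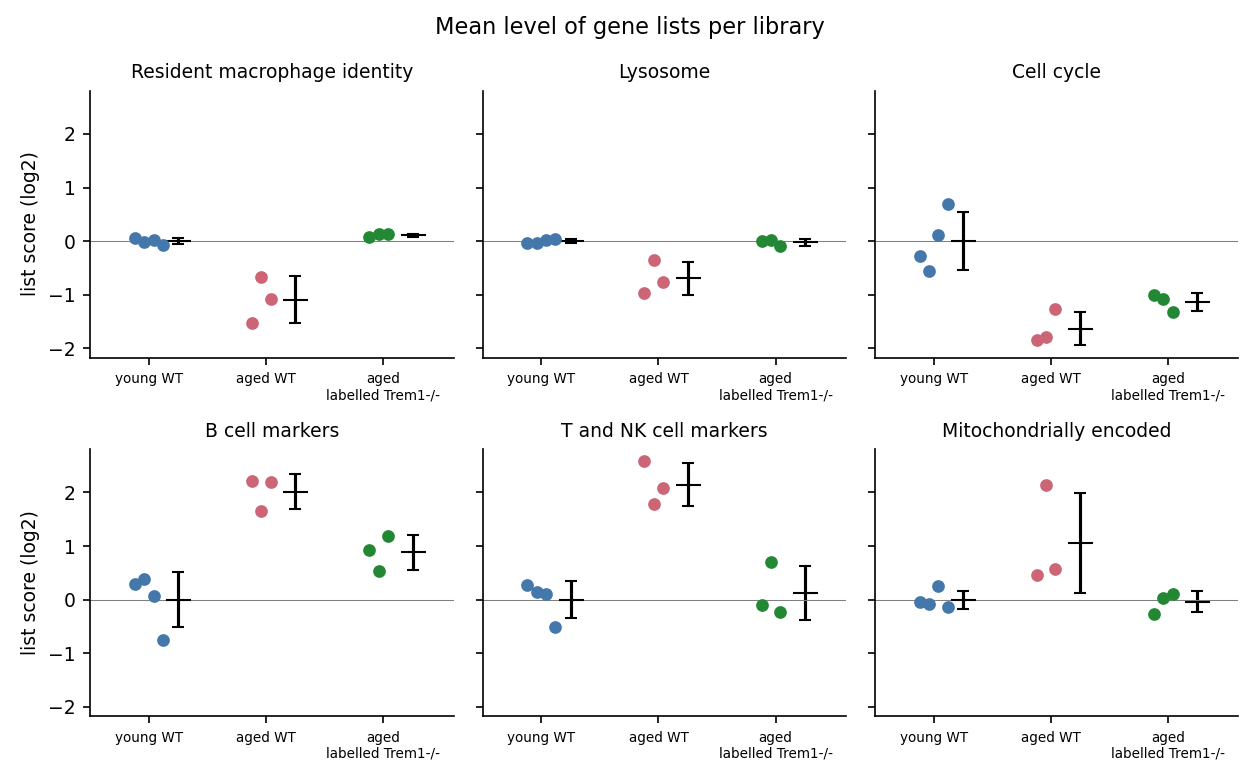
Scores of gene lists per library (points) with group means and SD, as the mean log2 level of a list's members relative to the young wild-type mean. B cell scores lie at 1.65 to 2.22 in aged wild type and 0.54 to 1.19 in the libraries labelled Trem1-/-, and resident macrophage scores at -1.53 to -0.66 and 0.07 to 0.13.

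The comparison of aged Trem1-/- with aged wild type asks how the aged macrophage transcriptome differs with the labelled genotype. Resident macrophage, phagocytic, lysosomal and antioxidant genes were higher in the libraries labelled Trem1-/-, and markers of T cells, B cells and red cells were lower. F5 had 11334 ± 1418 normalized counts against 3361 ± 1102 in aged wild type (log2 fold change 1.80 ± 0.21, limma adjusted p = 0.0013). Hmox1 had 444 ± 131 against 140 ± 59.4 (1.70 ± 0.27), and Lck 13.2 ± 5.44 against 82.5 ± 38.4 (-2.54 ± 0.37). With limma 1327 genes were higher and 785 lower, together 18.4% of those tested, and 423 and 402 of them differed more than 2-fold.

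Among the largest rises was Pi16, a peptidase inhibitor (chromosome 17, 29317680 to 29330593), from 80.4 ± 20.05 in aged wild type to 311 ± 24.6 (1.97 ± 0.18, limma adjusted p = 0.000619). Zbtb16, a transcription factor of innate-like lymphocytes, had 405 ± 220 against 68.8 ± 19.4 (2.37 ± 0.46). Hgf, hepatocyte growth factor, had 64.7 ± 16.3 against 16.3 ± 6.62 (1.96 ± 0.29), and Fzd1, a Wnt receptor, rose by 2.11 ± 0.32. Map3k6, Tppp3 and Gprc5b rose by 2.25 ± 0.50, 2.03 ± 0.27 and 2.03 ± 0.26; Gprc5b overlaps Iqck. Rab44, Mmp19 and Arl11 passed with all libraries (1.88 to 2.03) and lost their calls without single ones. Rab44 lost it without any of the young libraries, without aged wild-type replicate 3 or without Trem1-/- replicate 1 or 2 (adjusted p up to 0.14). Mmp19 lost it without aged wild-type replicate 3 or 6 or Trem1-/- replicate 2 (up to 0.0797), and Arl11 without young replicate A or C, aged wild-type replicate 3 or 6 or any Trem1-/- replicate (up to 0.108).

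The largest falls were led by globin and red cell genes, Hbb-bs, Hba-a1, Hba-a2, Hbb-bt and Alas2, the haem synthesis enzyme of red cells, with log2 fold changes of -6.35 to -5.49. Their level in aged wild type came mostly from replicate 4, and each lost its call without at least 1 library labelled Trem1-/-. Hbb-bs lost it without replicate 1, Hba-a1 and Alas2 without replicate 1 or 3, Hba-a2 without any of the 3 and Hbb-bt without replicate 3 (adjusted p up to 0.073). Hbb-bt had 3 reads against 1104, a ratio of 406 (exact 95% interval 138 to 1970). Aldh1a1, a retinal dehydrogenase, fell by 3.99 ± 1.13 and lost its call without aged wild-type replicate 3 or 6 or Trem1-/- replicate 1 or 3 (up to 0.0994). AF067061 fell by 3.97 ± 0.95 and lost it without aged wild-type replicate 3 or Trem1-/- replicate 1 or 2 (up to 0.0706). Trpm5, a cation channel of taste and tuft cells, fell by 3.92 ± 1.09 and lost it without Trem1-/- replicate 1 or 3 (up to 0.0831). Ehf, an epithelial transcription factor, fell by 3.54 ± 0.90 and lost it without Trem1-/- replicate 2 (up to 0.0687).

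Large peritoneal macrophage genes rose in 19 of 23 members (21 adjusted over the list alone; camera adjusted p = 1.58e-12, and adjusted p = 0.342 with an estimated correlation). Adgre1 had 4569 ± 300 normalized counts against 2115 ± 371 in aged wild type, and Ltbp1, which binds latent TGF-beta, rose by 1.49 ± 0.20. Lysosomal genes rose in 18 of 28 members (24 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.27e-09, and adjusted p = 0.49 with an estimated correlation). Man2b1, Grn and Gaa, a mannosidase, progranulin and acid glucosidase, rose by 1.17 ± 0.15, 1.11 ± 0.15 and 1.02 ± 0.14. Phagocytic receptors and complement rose in 15 of 25 members (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.83e-07, and adjusted p = 0.49 with an estimated correlation). Cfp, properdin, rose by 1.36 ± 0.19 and Mertk, a receptor for dying cells, by 1.24 ± 0.23. NRF2 antioxidant genes rose in 9 of 19 members (12 adjusted over the list alone; camera adjusted p = 0.000299, and adjusted p = 0.499 with an estimated correlation), Gsr, glutathione reductase, by 1.16 ± 0.25. Cholesterol efflux and lipid storage genes rose in 6 of 17 members (8 adjusted over the list alone; camera adjusted p = 0.000314, and adjusted p = 0.49 with an estimated correlation), Fabp4 by 1.71 ± 0.24 and Npc2, a lysosomal cholesterol carrier, by 0.90 ± 0.13. Glycolysis genes rose in 7 of 21 members and fell in 1 (14 and 2 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.499 with an estimated correlation), Hk1 by 0.65 ± 0.13. Senescence-associated genes rose in 3 of 14 members (3 adjusted over the list alone; camera adjusted p = 0.0275, and adjusted p = 0.499 with an estimated correlation), Glb1 by 1.30 ± 0.19. The senescence list lost its call without Trem1-/- replicate 2 (adjusted p = 0.0575). Glb1 is also in the lysosome list, so the rises of these lists are not independent. Oxidative phosphorylation passed with 1 of 48 members higher, a call that was not kept when adjusted over the list alone (camera adjusted p = 0.0275, and adjusted p = 0.694 with an estimated correlation) and lost its call without aged wild-type replicate 3 or 6 or Trem1-/- replicate 1 (adjusted p up to 0.226).

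T and NK cell markers fell in 10 of 13 members (12 adjusted over the list alone; camera adjusted p = 2.41e-08, and adjusted p = 0.342 with an estimated correlation). Bcl11b, a T lineage transcription factor, and Cd3g, a chain of the T cell receptor complex, fell by 2.41 ± 0.39 and 2.01 ± 0.38 on the log2 scale. B cell markers fell in 9 of 19 members (18 adjusted over the list alone; camera adjusted p = 2.77e-08, and adjusted p = 0.49 with an estimated correlation), Bank1, a B cell scaffold protein, by 1.04 ± 0.21. Mitochondrially encoded transcripts fell in 5 of 13 members (12 adjusted over the list alone; camera adjusted p = 9.28e-06, and adjusted p = 0.499 with an estimated correlation). Among them mt-Nd6, of complex I, fell by 1.09 ± 0.29, a call lost without Trem1-/- replicate 1 or 2 (adjusted p up to 0.0848). The size of the fall rested largely on aged wild-type replicate 4, with list scores of 0.464, 2.14 and 0.57 in aged wild-type replicates 3, 4 and 6 and of -0.26 to 0.115 in the libraries labelled Trem1-/-. Erythroid markers fell in 5 of 6 members (6 adjusted over the list alone; camera adjusted p = 0.000314, and adjusted p = 0.499 with an estimated correlation). Genes of the NAD and kynurenine pathway fell in 5 of 15 members and rose in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0201, and adjusted p = 0.342 with an estimated correlation). Kynu and Kmo fell by 1.81 ± 0.37 and 1.17 ± 0.22. MHC class II genes fell in 2 of 15 members and rose in 1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0201, and adjusted p = 0.535 with an estimated correlation), a call lost without aged wild-type replicate 6 (adjusted p = 0.0681). Mesothelial and fibroblast markers fell in 1 of 9 members (1 adjusted over the list alone; camera adjusted p = 0.0211, and adjusted p = 0.619 with an estimated correlation), a call lost without Trem1-/- replicate 1 or 3 (adjusted p up to 0.129). The fall rested on these libraries, with list scores of -1.38 and -0.597, since replicate 2 scored 3.21, within the range of aged wild type.

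The other 17 lists did not pass with camera, at adjusted p values of 0.0579 to 0.89. Of these, small peritoneal macrophage, mast cell, cholesterol synthesis and cell cycle genes passed after TMM rescaling or with some library left out, and TREM1 receptor signalling passed with fry (higher, adjusted p = 0.0363). Cell cycle genes had a median of 0.69 with 1 of 26 higher (adjusted p = 0.0579). TREM1 receptor signalling (adjusted p = 0.567) had 4 members higher and 2 lower (6 and 3 adjusted over the list alone). Tyrobp rose by 1.03 ± 0.16, Cd177, a neutrophil surface protein, by 1.43 ± 0.22 and Vav3, a signalling adaptor, by 1.203 ± 0.23. For inflammatory mediators (median 0.21, mean -0.24) and for immediate-early and heat-shock genes (median -0.06, mean 0.10) median and mean differed in sign. Srebf2, the master regulator of cholesterol synthesis, fell by 1.03 ± 0.18.

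Calls of this comparison moved with the shared estimate of the spread and with single libraries. A fit of the 2 aged groups alone called 726 genes higher and 445 lower. Higher and lower genes numbered 762 and 315 without aged wild-type replicate 3, 843 and 347 without replicate 6, 872 and 432 without Trem1-/- replicate 1 and 777 and 332 without replicate 2, and 7 of the 20 genes with the largest changes kept their call whichever library was left out.

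Changes with age and differences by genotype ran in opposite directions across genes. Of the 1647 genes that rose in aged wild type, 676 (41.0%) were lower in the libraries labelled Trem1-/- than in aged wild type, and of the 2190 that fell, 1138 (52.0%) were higher. Lck, Kynu and Blnk were among the former, and Adgre1, F5, Hmox1 and Fabp4 among the latter. Together 1814 genes ran in opposite directions and 0 in the same direction by limma. In 100 simulations of unchanged groups both numbers were 0, but few genes passed there, and the shared aged wild-type libraries by themselves favor opposite calls, so the counts alone do not show a reversal. The log2 fold changes correlated across genes with Pearson's r of -0.83 (Spearman's rho -0.84), although genes are not independent replicates. Both comparisons use the same aged wild-type libraries, which by itself gives a negative r, on average -0.54 in simulations of unchanged groups (range -0.92 to 0.42). The covariance of -0.45 lay beyond the simulated values (mean -0.06, lowest -0.22). Those simulations pooled the spread of the 3 groups. Replicates of aged wild type correlated at 0.917 to 0.953, those of young wild type at 0.954 to 0.975 and those labelled Trem1-/- at 0.948 to 0.963. The simulated shared part may therefore be too small, and an excess over it is not shown. The 3 aged wild-type libraries cannot be split into parts of at least 2, so part of the negative covariance may come from what these libraries share. The number of opposite genes was 936 without aged wild-type replicate 3, 1031 without replicate 6 and 2482 without replicate 4.

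**Figure D4:**
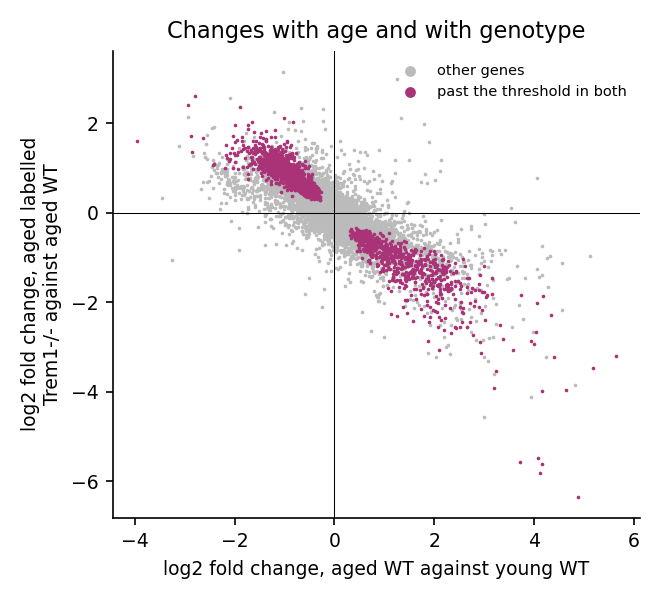
Log2 fold change of each tested gene in aged against young wild type (horizontal) and in aged libraries labelled Trem1-/- against aged wild type (vertical), with genes past the threshold in both colored. The colored genes, 1814, lie at the upper left and the lower right.

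The comparison of aged Trem1-/- with young wild type asks what remains different from the young state, with age and genotype changed together. As lists, cell cycle genes were lower and B cell markers and clock genes higher in the libraries labelled Trem1-/- by camera with the preset correlation, with 2 of 26, 3 of 19 and 0 of 15 single members called, and no list passed with an estimated correlation. With fry only clock genes (higher, adjusted p = 0.0403) and cholesterol synthesis genes (lower, 0.0377) passed. Cell cycle genes (fry adjusted p = 0.0611) and B cell markers (0.135) did not. Large peritoneal macrophage genes had a median log2 fold change of 0.12. Chit1, the chitinase of activated macrophages, had 31.8 ± 6.17 normalized counts against 0.154 ± 0.308 in young wild type (4.84 ± 0.56, limma adjusted p = 0.00819), from 96 reads against 1, a ratio of 138 (exact 95% interval 24.2 to 5519). Shank3 fell from 358 ± 139 to 64.3 ± 10.6 (-2.35 ± 0.40). With limma 68 genes were higher and 38 lower, 0.921% of those tested; 52 and 34 of them differed more than 2-fold, and 1654 genes had an unadjusted p under 0.05. Of these 106 genes, 90 also changed in the same direction in aged wild type, 29 differed between the aged groups and 4 did neither; the libraries these comparisons share by themselves favor such overlap, so the numbers are no test of it.

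The largest rises beside Chit1 included those of Cacna1h, a calcium channel (3.64 ± 0.71), Cubn, an endocytic receptor (3.43 ± 0.43), and Gnb3, a G protein subunit (3.35 ± 0.50). The largest falls were Apoc1, an apolipoprotein (-4.31 ± 0.72), Erc2, a scaffold of synapses (-2.74 ± 0.43), Shank3, Mxd3, a partner of MAX (-2.24 ± 0.43), and Ryr2, a calcium release channel (-2.04 ± 0.35). Mxd3 overlaps Prelid1. Cxcl13, a chemokine that attracts B cells, had 3788 ± 1738 normalized counts against 707 ± 307 in young and 1532 ± 173 in aged wild type (2.40 ± 0.36 against young). C3, the central complement protein, rose by 1.03 ± 0.19 and H6pd, of the pentose phosphate pathway in the endoplasmic reticulum, by 0.87 ± 0.14. Each named gene called here lost its call without Trem1-/- replicate 3, and Chit1 and Cubn only there (adjusted p = 0.0541). Cxcl13 and Gnb3 lost it also without young replicate C and Gnb3 without Trem1-/- replicate 1, and Erc2 also without young replicate A or C (adjusted p up to 0.103). Apoc1, Shank3, Ryr2 and H6pd lost it also without Trem1-/- replicate 1 or young replicate A, all but H6pd without young replicate C, Ryr2 and H6pd without young replicate E, and Shank3 without Trem1-/- replicate 2 (up to 0.111). Cacna1h, Mxd3 and C3 lost it in 7 or 8 of the 10 fits that left 1 library out, in each case without Trem1-/- replicates 1 to 3, aged wild-type replicate 6 and young replicates B and E, with young replicate A for Cacna1h and Mxd3 and young replicate C for Mxd3 and C3 (up to 0.122).

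Cell cycle genes fell in 2 of 26 members (24 adjusted over the list alone; camera adjusted p = 6.02e-22, and adjusted p = 0.352 with an estimated correlation), with a median of -1.24. Mcm7, of the replication helicase, and Tk1, thymidine kinase, fell by 1.17 ± 0.19 and 1.03 ± 0.21; Mcm7 overlaps Ap4m1 and Cops6. Without Trem1-/- replicate 1, 2 or 3 or young replicate C both lost their calls, and Tk1 also without young replicate A, B or E or aged wild-type replicate 6 (adjusted p up to 0.166). B cell markers rose in 3 of 19 members (12 adjusted over the list alone; camera adjusted p = 1.11e-10, and adjusted p = 0.461 with an estimated correlation), Ighd by 1.44 ± 0.29, Blk by 1.40 ± 0.27 and Pou2af1, a B cell coactivator, by 1.01 ± 0.19. These calls were lost without Trem1-/- replicate 1, 2 or 3, aged wild-type replicate 6 or young replicate C, those of Ighd and Blk also without young replicate E, that of Ighd without young replicate B and those of Blk and Pou2af1 without young replicate A (adjusted p up to 0.151). In 6 further lists that passed, limma called 0 single members over all genes, as did edgeR, and limma-voom called 2 cholesterol synthesis, 2 clock and 1 MHC class II gene. Cholesterol synthesis genes were lower with a median of -0.46 (3 adjusted over the list alone, 10 at an unadjusted p under 0.05, 2 by DESeq2; camera adjusted p = 2.18e-05, and adjusted p = 0.248 with an estimated correlation). Clock genes were higher with a median of 0.77 (7 higher and 1 lower adjusted over the list alone, 10 at an unadjusted p under 0.05, 3 by DESeq2; camera adjusted p = 9.23e-05, and adjusted p = 0.248 with an estimated correlation). Per2, a clock repressor, had 52.2 ± 31.5 against 14.7 ± 7.62 (limma adjusted p = 0.0767). MHC class II genes were higher with a median of 0.38 (6 adjusted over the list alone, 6 unadjusted, 2 by DESeq2; camera adjusted p = 0.00714, and adjusted p = 0.782 with an estimated correlation). Oxidative phosphorylation genes were lower with a median of -0.16 (3 unadjusted, 1 by DESeq2; camera adjusted p = 2.14e-05, and adjusted p = 0.782 with an estimated correlation). Purine synthesis genes had a median of -0.16 (3 unadjusted, 0 by DESeq2; camera adjusted p = 0.00714, and adjusted p = 0.674 with an estimated correlation), a call lost without young replicate E (adjusted p = 0.0739). Immediate-early and heat-shock genes had a median of 0.46 (4 unadjusted, 0 by DESeq2; camera adjusted p = 0.00714, and adjusted p = 0.955 with an estimated correlation), a call lost without young replicate B or Trem1-/- replicate 2 (adjusted p up to 0.855). For these 3 lists 0 members passed adjusted over the list alone.

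The other 24 lists did not pass (camera adjusted p = 0.0926 to 0.916), among them large peritoneal macrophage genes (0.835), lysosomal genes (0.641), phagocytic receptors and complement (0.626), T and NK cell markers (0.641) and TREM1 receptor signalling (0.149). Of the 24 lists, the TCA cycle, NRF2 antioxidant genes and mast cell, mesothelial and fibroblast, and erythroid markers passed after TMM rescaling or with some library left out. Median, mean and test differed in sign for Trem1 chromosomal neighbours, glycolysis, the pentose phosphate pathway, inflammatory mediators, cholesterol efflux, and arginase and alternative activation. The number of calls rested on single libraries. It was 0 with limma without Trem1-/- replicate 3 (1268 genes at an unadjusted p under 0.05), 14 without replicate 1, 58 without replicate 2, and 29, 21 and 33 without young replicates A, C and E; without aged wild-type replicates 3, 4 and 6, which enter through the shared estimate of the spread, it was 200, 268 and 58.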

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

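All tests weighed in this part, apart from the one on reads from genomic DNA, were chosen after the result was seen.

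Aged wild-type libraries stood apart from both other groups. A lower share of macrophage RNA stays open for their difference from young wild type: pan-macrophage markers had a median log2 fold change of -1.002 against young wild type (12 of 16 lower, quartiles -1.19 to -0.81), Lyz2 falling from 58049 ± 2943 to 22405 ± 5009 normalized counts, while the medians of B cell, T and NK cell, mast cell, and mesothelial and fibroblast markers lay within 0.565 of each other at 1.98 to 2.54. Mast cell and mesothelial and fibroblast markers weigh little here, because their scores in young replicate C (1.88 and 3.01) and Trem1-/- replicate 2 (2.196 and 3.21) lay within the range of aged wild type, while resident macrophage scores there were 0.0241 and 0.127. Abundant among these markers of other cells were Ighm (2152 ± 617 in young, 9072 ± 2172 in aged wild type) and Igkc (512 ± 151 and 1959 ± 1221). Young libraries also held 19 of 20 B cell, 5 of 22 T and NK cell, 7 of 11 mast cell and 5 of 15 mesothelial and fibroblast genes at a mean of at least 10. None of these genes was in another list, whereas 7 of the 18 pan-macrophage genes were. The pan-macrophage list was not among the 34 fixed lists. It shares Adgre1 and C1qc with the resident macrophage and phagocytic lists, so their falls are not independent. The labels name no sort that would remove the other cells. For their difference from the libraries labelled Trem1-/- a lower share also stays open, with pan-macrophage markers at 0.886. B cell markers had a median of -1.08 (quartiles -1.23 to -0.984) and T and NK cell markers -2.05 (-2.41 to -1.88), 0.97 apart, and the 4 lists spanned 1.07, which counts against a share alone. Per library, however, the B cell minus T and NK cell score was 1.03 and 1.41 in Trem1-/- replicates 1 and 3 and -0.159 in replicate 2, within the -0.368 to 0.11 of aged wild type, and the full span includes the lists that weigh little, so neither decides. Reads from genomic DNA are argued against for replicate 4, where 1438 olfactory and vomeronasal receptor genes had a summed CPM of 130 against 84.8 to 201 in the other groups, but replicates 3 and 6 lay above that range at 299 and 261. Genes with reads numbered 25423 and 26032 in replicates 3 and 6 and 21323 in replicate 4, against 18421 to 22690 in the other groups. Genomic DNA therefore stays open for replicates 3 and 6. Trends of GC content and transcript length are argued against as the whole cause, since 3641 of 3837 calls of aged against young wild type remained in the same direction after their removal. Age and genotype as biological causes, and a change in the other cells themselves, stay open and untested, because dendritic cell markers (median -0.11, members both ways) and erythroid markers (4.10, resting on replicate 4) decide nothing. A difference in RNA quality or preparation was not tested and also stays open, since the labels name no batch. In aged wild type Gm26917 took 8.38% to 12.9% of reads and mitochondrial transcripts 3.17% to 5.26%. Other libraries reached at most 5.70% and 2.39%.

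Cell cycle genes were lower in both aged groups than in young wild type. For the libraries labelled Trem1-/- a lower share of macrophage RNA alone is argued against, since the median of pan-macrophage markers lay 1.17 above that of cell cycle genes (-0.07 and -1.24), and the same gap of scores was 0.853 to 1.21 in these libraries and -0.719 to 0.542 in young ones. For aged wild type it stays open: the medians lay 0.884 apart, but the gap was 1.32 in replicate 4 and 0.586 and 0.278 in replicates 3 and 6, so the ranges of aged and young libraries overlapped. In the libraries labelled Trem1-/- 24 of 26 members had a limma unadjusted p under 0.05. DESeq2 called 18 of them against young wild type, but limma called 2, edgeR 1 and limma-voom 3. Less division with age remains a candidate explanation, which these data found and cannot test apart from other differences between young and aged preparations.

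Trem1 reads appeared in libraries labelled Trem1-/-. Reads of an overlapping gene are argued against, since 0 annotated genes share its exonic bases. A swap of single libraries between the aged groups is argued against, since 0 of the 6 aged libraries correlated best with a library of the other group. A wrong label for the whole set, or a swap with an outside sample, was not tested. An allele that keeps part of the transcript could give a ratio of 1.35 to aged wild type, and it stays open because counts per gene do not show exons.

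Other groupings of the same libraries were counted for each comparison. For aged against young wild type 1 of 35 splits, the real one, gave as many calls (3837, highest other 0 by limma). For the libraries labelled Trem1-/- against young wild type it was again 1 of 35 (106, highest other 4). That is the smallest share 35 splits allow. Splits that mix differing groups also widen the spread and so give few calls, so these counts do not exclude chance in either comparison. The 106 calls fell to 0 without Trem1-/- replicate 3. For the 2 aged groups 10 splits are too few for a share under 0.05, with 2112 calls in the real split and at most 4 in the others.

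Single values far from the other libraries of their group were found in 13 of 85 values checked, all in young wild type, the only group large enough for the check; chance gives about 5%. Listed here are 12 of them. Young replicate C had 0.0196% of reads on alpha- and beta-globin genes, where the others had 0.000256% to 0.00279%. In the same library Hba-a1 had 372 normalized counts (others 4.65 to 54.0), Hba-a2 232 (2.32 to 24.6), Hbb-bt 30.02 (1.16 to 4.31) and Alas2 58.8 (1.16 to 9.59). Aldh1a1 had 8.41 there (others 0 to 1.16), Krt18 14.4 (1.74 to 2.46) and Zbtb16 454 (199 to 214). Young replicate E had a score of 0.22 on the integrated stress response list (others -0.083 to -0.057), 151 normalized counts of Shank3 (407 to 455) and 74.4 of Mmp19 (43.6 to 46.8). Young replicate B held the only Chit1 read of its group, at 0.616 normalized counts.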

How the results depend on the processing

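Tests with edgeR and TMM factors, TMM rescaling, the GC and length correction, the removal of genes of other cell types and the removal of aged wild-type replicate 4 together with Trem1-/- replicate 2 were chosen after seeing the data. The correlation across genes stayed negative in every setting run (DESeq2 -0.718; -0.867 to -0.804 without single aged wild-type libraries). No call of a named gene or list reversed. Of the named gene calls, DESeq2 kept 251 of 255, edgeR with TMM 252 of 263, limma-voom 241 of 263, the fits of only the 2 groups compared 218 of 265 and the GC and length correction 256 of 265. Of the 39 list calls TMM rescaling kept 39, fry 23 and camera with an estimated correlation 0 (unadjusted p under 0.05 in 2, 3 and 3 lists of the 3 comparisons). Limma-voom called 2796 genes higher and 2861 lower in aged wild type than in young, 2076 higher and 1835 lower in libraries labelled Trem1-/- against aged wild type, and 134 and 82 against young wild type; the cause was not tested. A fold threshold, which leaves fewer genes by construction, gave 880 higher and 834 lower for age, and 423 and 402 between the aged groups. Fits of only the 2 groups gave 726 and 445 between the aged groups, where the main fit gave 1327 and 785. For Trem1-/- against young wild type they gave 154 and 145, where the main fit gave 68 and 38. Fewer libraries do not account for that rise. The main fit shares 1 estimate of the spread over the 3 groups, so its counts depend on the group not compared. For Trem1-/- against young wild type no filter gave 161 and 102 and DESeq2 256 and 175. Leaving out aged wild-type replicate 4 with Trem1-/- replicate 2 gave 176 and 71 there, and the cause was not tested. Camera with an estimated correlation called 0 lists in either direction in each comparison. Fry called 4 lists higher and 10 lower for age, and 7 higher and 3 lower between the aged groups. It called 1 list higher, clock genes, and 1 lower, cholesterol synthesis genes, for Trem1-/- against young wild type. With any 1 library left out, calls between the aged groups ranged from 762 to 1785 higher and 315 to 1015 lower, calls for Trem1-/- against young wild type from 0 (without Trem1-/- replicate 3, limma; 1268 at an unadjusted p under 0.05) to 159 higher and from 0 to 109 lower, and genes opposite in age and genotype from 936 to 2482. For age they ranged from 1149 to 1744 higher and 1591 to 2417 lower. The Trem1 ratio ranged from 0.526 (reversed, without Trem1-/- replicate 2) to 2.26, with 1.24 by CPM and 1.41 by CPM with TMM. TMM rescaling moved the median log2 fold change by -0.068, 0.060 and -0.0079 and the share of calls that were higher from 42.9% to 35.1% for age, from 62.8% to 72.0% between the aged groups and from 64.2% to 61.2% for the third comparison. The authors' comparison covered age alone, so it was not run for the other two. No paired analysis was possible because the aged groups share only the number 3. At this depth, and with few genes changed, 2-fold changes were recovered in 47.8% to 55.2% of simulated genes, so genes that did not pass are not shown to be unchanged.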

Other observations

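The B cell score covariate was chosen after the result was seen, and the test of genes around Trem1 was chosen before.

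Clock genes changed in aged wild type in both directions, and the list as a whole did not pass (camera adjusted p = 0.312). Cry1, a repressor of the clock, rose from 14.1 ± 5.50 to 58.8 ± 15.3 normalized counts (n = 4 and 3) and Bhlhe41, another repressor, from 74.5 ± 21.2 to 337 ± 69.3. B cell markers rose in the same libraries, and which cells carried these reads was not tested. Arntl and Clock, the activating pair, fell by 0.75 ± 0.20 and 0.42 ± 0.11 on the log2 scale. In the libraries labelled Trem1-/- Cry1 and Bhlhe41 had 27.5 ± 1.86 and 145 ± 70.0. Against aged wild type both calls were lost without aged wild-type replicate 3 or 6 or Trem1-/- replicate 2, and that of Cry1 also without young replicate C or Trem1-/- replicate 1 or 3 (limma adjusted p up to 0.143).

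Single genes of activation programmes moved where their lists did not. B and T cell markers also rose in aged wild type, and which cells carried the reads of these genes was not tested. In aged wild type Pdcd1lg2, the checkpoint ligand PD-L2, rose from 10.9 ± 4.46 to 77.0 ± 33.2 and Il4ra, the interleukin 4 receptor, by 0.91 ± 0.21 on the log2 scale, while Mgl2, a lectin of alternatively activated macrophages, fell from 86.2 ± 11 to 14.2 ± 4.90. Ccl5, a chemokine also made by T cells, rose from 11.1 ± 8.13 to 81.4 ± 26.9, beside the rise of T cell markers. Among interferon-stimulated genes Bst2 fell by 1.03 ± 0.19 and Ddx58, which encodes the RNA sensor RIG-I, rose by 0.72 ± 0.14. Cebpb, a transcription factor of myeloid cells, fell by 1.30 ± 0.24 and was higher by 1.37 ± 0.25 in the libraries labelled Trem1-/- than in aged wild type; its exons overlap Tmem189. Phgdh, the first enzyme of serine synthesis, rose by 1.89 ± 0.33. Gm7901 shares 58.99% of the sequence of Phgdh, and Clec10a 22.55% of that of Mgl2.

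Genes near Trem1 were tested for foreign flanking DNA, which a targeted allele may carry from another strain. Within 10 Mb of Trem1, 7 of 123 genes (5.69%) differed in the same direction from both wild-type groups in the libraries labelled Trem1-/- (limma, unadjusted p under 0.05 in each), against 267 of 11309 (2.36%) elsewhere (one-sided Fisher exact p = 0.0284). They were Mrps10, C3, CT010467.1, Rfx2, Plcl2, Lrg1 and Enpp5, chosen by position and not by the rule for named genes. Differences of these genes could come from the flanks, from the targeted allele itself or from chance, since 2.36% of genes elsewhere also differed. The Fisher test treats neighbouring genes as independent, and both comparisons share the same Trem1-/- libraries. Foreign flanks remain a hypothesis that sequence variants would test and that gene counts cannot.

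With the B cell marker score as a covariate, limma called 0 genes for age (827 at an unadjusted p under 0.05), 0 between the aged groups (1386) and 1 for Trem1-/- against young wild type (1045). Among the genes called without it, the median absolute log2 fold change went from 0.91 to 0.42 and the median SE from 0.20 to 0.45 for age, and from 0.87 to 0.55 and 0.19 to 0.27 between the aged groups. Groups held 85.1% of the variance of the score, so calls ended from wider errors as well as smaller folds, and the covariate cannot separate group from composition.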
